A study of Mus musculus with 9 samples.

How the data were processed

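Polyadenylated RNA was sequenced from sorted mouse liver endothelial cells of 9 samples, 4 labelled control and 5 labelled Erg and Fli1 double knockout, taken at day 7 after tamoxifen. Per the labels' protocols, a VE-cadherin antibody was injected into the living mice, the tissue was dissociated with collagenase and dispase, and live cells negative for CD45 and positive for CD31 and VE-cadherin were sorted. Per the labels, libraries were made with either an unstranded or a stranded TruSeq kit, and which kit was used for which library is not stated. The authors deposited 1 table of raw counts per Ensembl gene, with 52636 rows and 1 column per sample. Per the submitters' processing notes, FastQC 0.11.5, STAR 2.7.6a and the build GRCm38 were named, and the counting program, the annotation release and the strand setting are not given in the sources used here. If a counting program ignored strand, reads of overlapping genes on opposite strands would be merged. Of the 22 targeted and top genes, 14 overlap another annotated gene, and for 6 of them (Ackr4, Ccdc88c, Fli1, Flrt1, Lrrn3 and Tnfrsf9) the other gene was itself tested.

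Sample groups and replicate numbers were taken from the sample titles. Column names of the count table were matched to the sample descriptions, and 0 columns were left unused. Both sexes were found in each group, so each group holds at least 2 animals, but nothing in the labels says that every sample came from its own animal, and p-values measure only the spread between these samples, part of which may be technical. Library pairs within a group differed by far more than sampling noise (chi-square per degree of freedom between 20.3 and 182, over genes with at least 10 counts in the pair), so no library was counted as a copy of another.

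Gene symbols, coordinates and overlaps came from the GENCODE annotation of GRCm38 supplied as a reference, which gave a symbol for 52403 of the identifiers and none for 233. Genes were filtered with filterByExpr by group (minimum count 10, minimum total 15), which left 14583 of them. Counts were scaled by TMM and tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation, then glmQLFTest, knockout-labelled over control, with no covariate and no replicate block), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The standard error of a log2 fold change was taken as its size over the square root of the quasi-likelihood F. A fold against a group with 0 counts was computed against a floor of 3 counts over the group. Such floors and the 95% intervals cover counting error only, because reads without molecular identifiers are not independent molecules. The libraries held between 26791371 and 36401682 counts, at which 1 count was worth between 0.0260 and 0.0368 CPM.

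The 30 gene lists, 22 of endothelial identity or pathways and 8 of markers for other cell types, were written before the data were examined, as were the design and the rule for the genes named. That rule took Erg and Fli1, then the 10 largest rises and the 10 largest falls among genes with an adjusted p under 0.05, a mean of at least 10 CPM and no overlap between the groups (names of predicted and RIKEN genes left out), and up to 4 members of each list with the smallest p. A member past the threshold against most of its list could be named as well. Some genes that the rule took are not reported here. Cdh5 and Pecam1 were added because they encode the proteins of the sort, and Wnt9b, Bgn, Itga2b and the genes of the closing section other than list members were named after their values were seen. Of all list members, 3 had no match in the annotation. The list of 52 imprinted genes, the gene families, the genes near the targeted loci and the Y-linked genes of the closing section were chosen for testing after the first results were seen. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, two-sided and adjusted over the lists, with camera under an estimated correlation and fry as alternatives. For the lists of continuous capillary and lymphatic genes the median and mean log2 fold change were positive and the test's direction negative. For NF-kB inflammation and angiogenesis the mean was positive and the median and the test's direction negative.

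The sex of each sample was read from whether Xist or the Y-linked gene Ddx3y had more counts: 3 controls and 2 libraries labelled knockout were male, and 1 control and 3 libraries labelled knockout were female. Alternatives tried were DESeq2 1.42.0 and limma-voom in place of edgeR, 3 other scalings, no count filter and a filter of 5 CPM in 4 samples, a test against a log2 fold change of 1, a replicate block and leaving out each library. A sex term and leaving out replicates 2 and 3 of the libraries labelled knockout together were added after seeing the data. On counts simulated for this comparison (14370 genes), the test recovered 68 of 100 genes changed 2-fold and 85 of 100 changed 4-fold, with 9 false calls. A planted list, all of whose members rose 2-fold, was recovered and 0 of 29 unchanged lists passed. The simulated genes varied independently of each other, so this does not cover lists whose members vary together. It does not cover lists that change only in part either. Far fewer genes were changed than were called in the data, so error under a broad shift was not checked. Figures were drawn with matplotlib 3.10.9.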

Results

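RNA was sequenced from endothelial cells of mouse liver, sorted as live, CD45-negative and CD31-positive cells that had also bound a VE-cadherin antibody injected before dissection. Erg and Fli1 encode ETS transcription factors of endothelial and blood cells, and the labels describe cells taken at day 7 after tamoxifen, which was given to induce deletion. The design holds 1 comparison, 5 libraries labelled as Erg and Fli1 double knockout against 4 control libraries labelled wild type. It asks which transcripts of adult liver endothelium differ when both factors are targeted. The deposited table held between 31613059 and 34663989 counts per control library and between 26791371 and 36401682 counts per library labelled knockout. Values are CPM, counts relative to the library total after TMM scaling, as mean ± SD unless another error is named.

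The 2 targeted genes went opposite ways. Erg (ENSMUSG00000040732, GRCm38 chromosome 16, 95359169 to 95586593, minus strand) fell from 311.6 ± 17.8 CPM (n = 4) to 142.9 ± 10.9 CPM (n = 5), and no library of one group reached the range of the other. Its log2 fold change was -1.12 ± 0.08 (SE), adjusted p = 2.61e-05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over all genes. Fli1 (ENSMUSG00000016087, chromosome 9, 32422204 to 32542861, minus strand) rose from 100.1 ± 8.01 to 147.4 ± 22.5 CPM, a log2 fold change of 0.56 ± 0.12 (SE, edgeR adjusted p = 0.00636), again without overlap between the groups. Gene-level counts of Fli1 showed no loss of its transcript, so the 5 libraries are called libraries labelled knockout throughout. Every direction below is relative to that label. Gene-level counts can keep reads of exons outside a deleted part, and the labels do not give the deleted exons, so these values do not show whether either protein was lost.

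**Figure D1:**
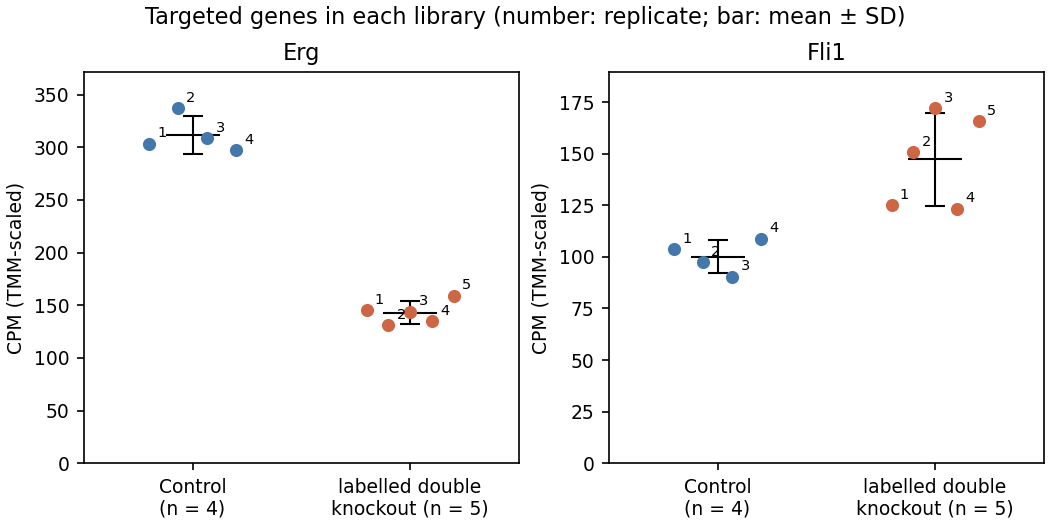
TMM-scaled CPM of Erg (left) and Fli1 (right) in each library, with the replicate number beside each point, for 4 control and 5 libraries labelled double knockout; horizontal bars are means and error bars are SDs. Erg fell from a mean of 311.6 to 142.9 CPM and Fli1 rose from 100.1 to 147.4 CPM, with no overlap between groups in either gene.

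Between the groups, 22 of 30 interferon response genes, 10 of 24 sinusoidal genes and 8 of 11 pericentral genes were lower in the libraries labelled knockout, and 11 of 21 glycolysis and hypoxia genes were higher. The lectin Clec4g fell from 3225 ± 375 to 455 ± 217 CPM, and the TAM receptor ligand Gas6 fell from 576 ± 96.7 to 54.9 ± 30.2 CPM. The metalloprotease Bmp1 rose from 1.12 ± 0.237 to 320 ± 173 CPM, and the plasminogen activator Plau rose from 141 ± 26.4 to 935 ± 358 CPM. The sort's own 2 endothelial proteins did not change detectably at the transcript level, among cells kept because both proteins were detected. Cdh5, which encodes VE-cadherin, lay at 2190 ± 113 and 2158 ± 193 CPM (log2 fold change -0.02 ± 0.11, SE). Pecam1, which encodes CD31, lay at 1482 ± 97.9 and 1408 ± 164 CPM (-0.07 ± 0.12, SE).

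Of 14583 genes tested, 2110 were higher and 2161 lower in the libraries labelled knockout at an adjusted p under 0.05 in edgeR's quasi-likelihood test, which is 29.3% of the genes. Of these, 834 higher and 815 lower genes changed at least 2-fold. The groups did not overlap for 3577 of the called genes and for 3938 of all tested genes, where chance gives 1.59% of genes for 4 against 5 libraries. The biological coefficient of variation was 26.3%, and the first principal component, which held 52.6% of the variance, separated the groups. On the second, which held 17.7%, replicates 2 and 3 of the libraries labelled knockout lay at 53.2 and 26.8. Replicates 1, 4 and 5 lay at -11.7, -39.5 and -46.2, and the controls between -16.3 and 20.4.

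The 10 largest rises started from control means of at most 2.22 CPM. Bmp1, which cleaves procollagens, rose 286-fold (log2 8.16 ± 0.55, SE, edgeR adjusted p = 2.42e-05). Chpf, a chondroitin polymerising enzyme, rose from 0.450 ± 0.104 to 88.2 ± 16.4 CPM, a log2 fold change of 7.60 ± 0.22 (SE). The calcium channel subunit gene Cacna1h had 13 control counts in all and reached 55.6 ± 78.7 CPM. The atypical cadherin gene Fat3 had 7 and reached 23.3 ± 18.2 CPM, and Lrrn3 had 9 and reached 21.5 ± 14.0 CPM. The fold changes of these 3 rest on few control reads. Nt5e, the ecto-enzyme that makes adenosine from AMP, rose from 2.22 ± 1.23 to 193 ± 151 CPM, and Plat, tissue plasminogen activator, from 1.25 ± 0.183 to 102 ± 105 CPM. The protease inhibitor gene A2m (89.5 ± 119 CPM), the TNF receptor family member Tnfrsf9 (44.7 ± 58.8 CPM) and the pregnancy-specific glycoprotein gene Psg22 (115 ± 136 CPM, one of a family of similar genes whose reads may be shared) completed the 10 largest. Several of these SDs exceeded the means because replicates 2 and 3 stood far above replicates 1, 4 and 5. Without those 2 libraries, an alternative added after seeing the data, the rises were 69.6-fold for Cacna1h, 9.21-fold for Tnfrsf9, 10.3-fold for A2m, 16.1-fold for Psg22, 20.4-fold for Plat and 46.5-fold for Nt5e, against 528-fold, 157-fold, 117-fold, 109-fold, 81.1-fold and 87.3-fold with all 5, and each kept its call in that fit. Other tests lost some of them: limma-voom ended the calls of Tnfrsf9 (adjusted p = 0.257), Cacna1h and A2m (0.229 each) and Psg22 (0.116), and the fit without a count filter ended that of Tnfrsf9 (edgeR adjusted p = 0.0597), as did glmTreat (0.0657). Over all alternatives the adjusted p of these 4 lay between 3.69e-12, for the Cacna1h log2 fold change in DESeq2, and 0.257. Leaving out replicate 3 alone gave 212-fold for Cacna1h, 87.1-fold for Tnfrsf9 and 57.3-fold for A2m, and leaving out replicate 2 alone gave 68.9-fold for Psg22.

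The 10 largest falls were of transcripts with control means of at least 29.5 CPM. The atypical chemokine receptor gene Ackr4 fell from 74.3 ± 15.5 to 1.42 ± 0.613 CPM, 52.6-fold lower (log2 -5.72 ± 0.31, SE, edgeR adjusted p = 8.96e-06). Ifitm10 fell from 30.1 ± 6.64 to 0.762 ± 0.378 CPM, and the butyrophilin-like gene Btnl9 from 712 ± 111 to 40.6 ± 47.9 CPM. Rasa4, a Ras GTPase-activating protein, fell 10.5-fold from 116 ± 13.9 CPM. Rab3b, a vesicle traffic GTPase, fell 15.9-fold, Flrt1 14.6-fold, the Dishevelled-binding protein gene Ccdc88c from 97.9 ± 16.4 to 7.48 ± 3.94 CPM, the secreted semaphorin gene Sema3d 10.6-fold and Pgm5 10.5-fold. Here replicates 2 and 3 kept more of 3 transcripts. Without them Btnl9 was 85.6-fold lower in place of 17.5-fold, Flrt1 49.6-fold and Ccdc88c 20.7-fold lower. Leaving out replicate 2 alone made Btnl9 31.9-fold lower.

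**Figure D2:**
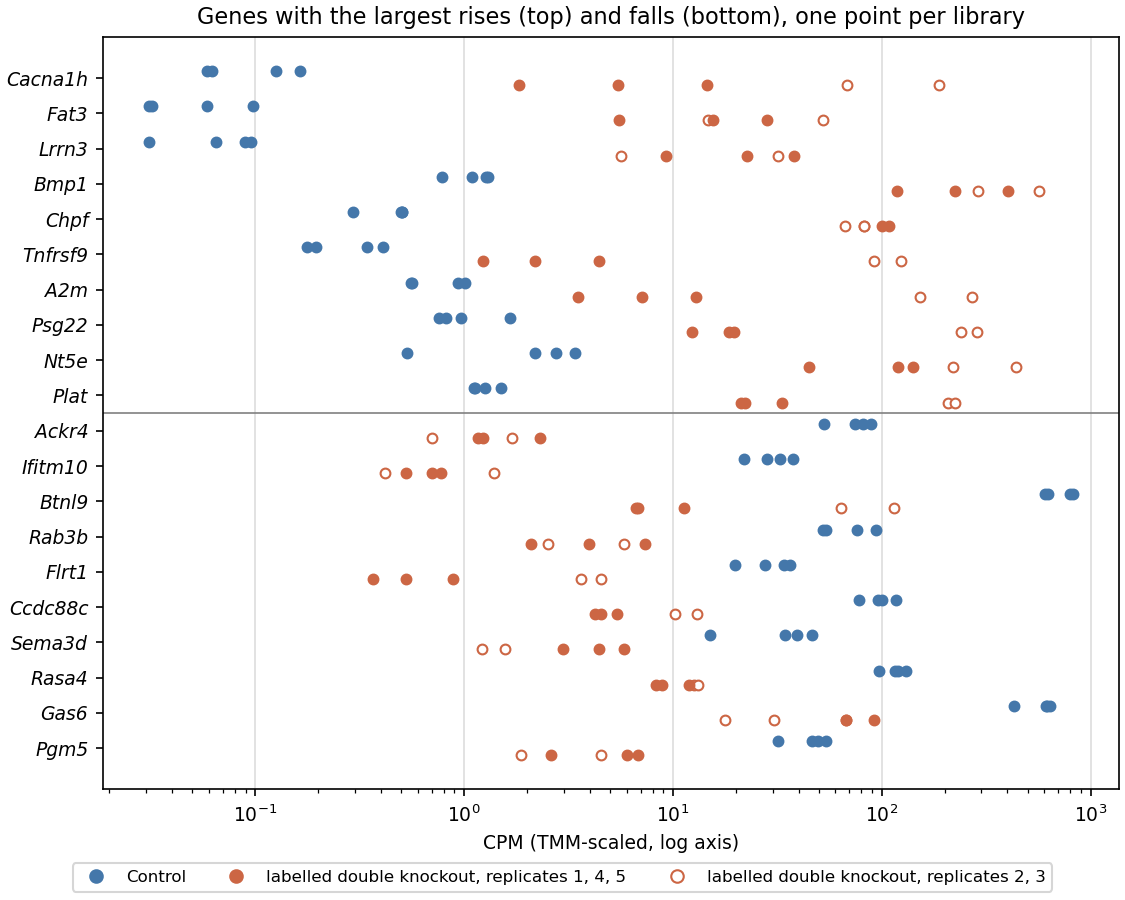
TMM-scaled CPM on a log axis of the 10 genes with the largest rises (upper part) and the 10 with the largest falls (lower part), one point per library: blue for 4 controls, orange for the libraries labelled double knockout, open for replicates 2 and 3. Cacna1h, Tnfrsf9, A2m, Psg22 and Plat show replicates 2 and 3 above replicates 1, 4 and 5. No gene shows overlap between the groups, which the rule that chose these genes required.

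Of 33 measured pan-endothelial genes, whose transcripts are shared by endothelium of most organs, 17 were lower, 3 higher and 13 not past the threshold (18 lower and 4 higher when adjusted over the list alone). The list passed camera with a preset correlation (adjusted p = 2.05e-05), though not with an estimated one (adjusted p = 0.160 with an estimated correlation). Ushbp1 fell 4.89-fold (1319 ± 203 to 270 ± 39.6 CPM), the extracellular matrix gene Mmrn2 2.96-fold and the VEGF receptor gene Flt1 2.90-fold. The 3 that rose were the transcription factor genes Lyl1 (22.5 ± 2.85 to 91.1 ± 18.3 CPM) and Tal1 (85.6 ± 7.57 to 134 ± 12.5 CPM) and the sphingosine phosphate receptor gene S1pr1 (194 ± 8.43 to 471 ± 210 CPM).

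Sinusoidal genes, which mark the fenestrated capillaries of the liver, included 10 lower and 2 higher of 24 measured (13 and 2 adjusted over the list alone, by DESeq2 and by limma-voom). The list test gave camera adjusted p = 2.37e-05, and adjusted p = 0.549 with an estimated correlation. The scavenger receptor gene Stab1 fell from 6236 ± 302 to 2422 ± 210 CPM, Cd300lg fell 9.42-fold, Cd209b 13.3-fold and Clec4g 7.08-fold. The lectin gene Clec1b (260 ± 44.5 to 495 ± 144 CPM) and the protease gene Lgmn (605 ± 124 to 967 ± 200 CPM) rose. The Lgmn call ended without control replicate 2, 3 or 4 or without replicate 1, 4 or 5 of the libraries labelled knockout, at edgeR adjusted p between 0.0516 and 0.0732.

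Pericentral genes, expressed by endothelium around the central vein, included 8 lower and 1 higher of 11 (the same counts adjusted over the list alone). Tested as a list, they gave camera adjusted p = 2.58e-05, and adjusted p = 0.386 with an estimated correlation. The Wnt pathway agonist Rspo3 fell from 78.7 ± 14.8 to 29.7 ± 4.61 CPM, Tcim 2.90-fold, the transcription factor gene Lhx6 5.75-fold and Gas6 10.5-fold. Wnt9b, a Wnt ligand named after its values were seen, fell from 98.9 ± 16.2 to 11.2 ± 12.8 CPM, 8.84-fold, or 17.9-fold without replicate 2 and 14.2-fold without replicates 2 and 3 of the libraries labelled knockout. The fatty acid carrier gene Fabp4 rose from 316 ± 38.0 to 1319 ± 512 CPM. Arterial genes included 7 lower and 0 higher of 19 (the same adjusted over the list alone). As a set they gave camera adjusted p = 0.0160, and adjusted p = 0.559 with an estimated correlation. Among them Ltbp4, which binds latent TGF-beta, fell from 3093 ± 518 to 347 ± 102 CPM, the gap junction gene Gja5 fell 20.7-fold from 8.15 ± 4.69 CPM, and Notch1 fell 1.89-fold. The arterial call ended without control replicate 4 (camera adjusted p = 0.0578).

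Of 30 measured interferon-stimulated genes, 22 were lower and 0 higher (27 lower adjusted over the list alone, 25 by DESeq2 and 21 by limma-voom). In the list test they gave camera adjusted p = 7.89e-11, and adjusted p = 0.549 with an estimated correlation. That correlation was 0.815 for this list, the members varying together between libraries. The antiviral gene Rsad2 fell from 278 ± 126 to 57.0 ± 12.4 CPM, Cmpk2 4.82-fold, the guanylate-binding protein gene Gbp2 5.02-fold and Trim30a 2.37-fold. Antigen presentation genes included 9 lower and 0 higher of 16 (the same adjusted over the list alone). For the whole list the test gave camera adjusted p = 2.05e-05, and adjusted p = 0.549 with an estimated correlation. The class I transactivator gene Nlrc5 fell 3.71-fold, the immunoproteasome genes Psmb8 and Psmb9 fell 2.30-fold and 2.88-fold, and the peptide transporter gene Tap2 fell 1.72-fold.

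Cell cycle genes included 6 lower and 0 higher of 30 (the same adjusted over the list alone and by limma-voom, but 13 lower by DESeq2). The list sum of control replicate 4, 608 CPM, lay within the 392 to 659 CPM of the libraries labelled knockout. The list test gave camera adjusted p = 3.47e-04, and adjusted p = 0.725 with an estimated correlation. The named members all serve DNA replication: Mcm3 fell 1.94-fold, Mcm6 1.86-fold, Pcna 1.41-fold and Mcm4 1.39-fold. Glycolysis and hypoxia-responsive genes included 11 higher and 0 lower of 21 (14 and 0 adjusted over the list alone, 15 and 0 by DESeq2, 9 and 0 by limma-voom). Tested as a list, they gave camera adjusted p = 7.69e-05, and adjusted p = 0.559 with an estimated correlation. The phosphofructokinase gene Pfkl rose from 84.5 ± 8.06 to 234 ± 46.4 CPM, the aldolase gene Aldoa 2.35-fold, the mitophagy receptor gene Bnip3 6.99-fold and Ndrg1 2.06-fold. Bnip3 rose 4.13-fold without replicates 2 and 3.

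**Figure D3:**
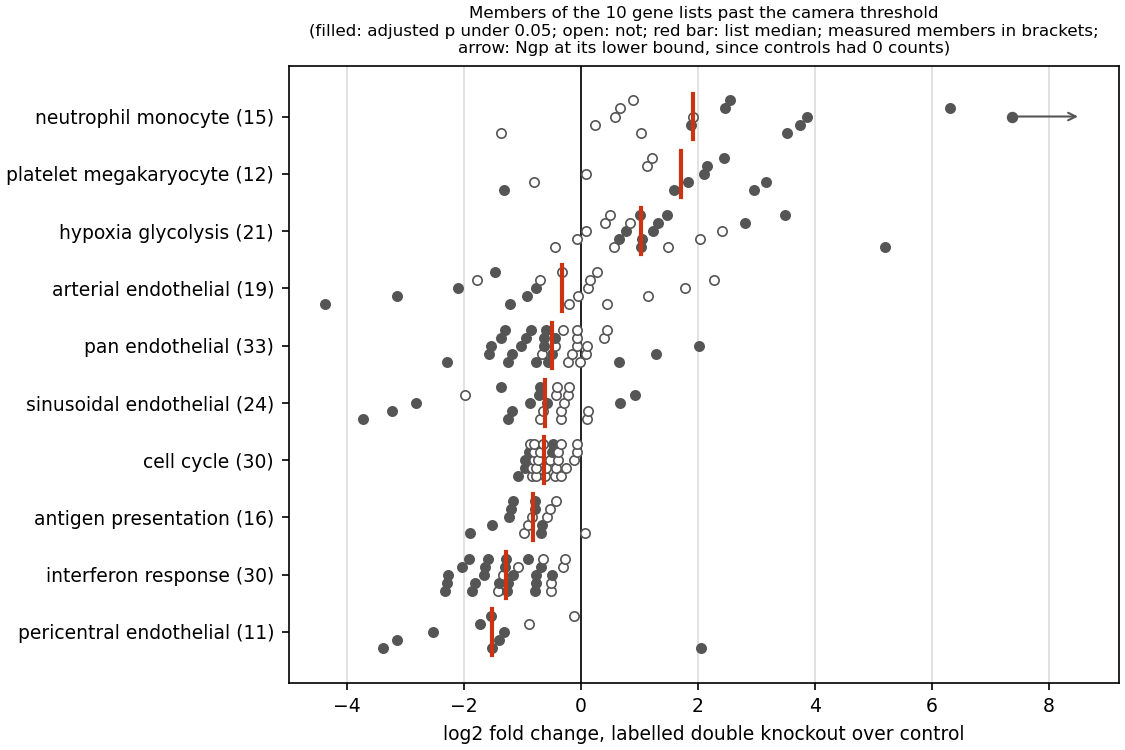
Log2 fold change (libraries labelled double knockout over control) of every measured member of the 10 lists that passed camera with a preset correlation; filled points passed the adjusted p threshold of 0.05, open points did not, and red bars are list medians. The interferon list has 22 members called lower and 0 higher, and the glycolysis and hypoxia list 11 higher and 0 lower. Ngp is drawn at its lower bound.

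Other pathway lists did not pass camera, and most of them held changed genes in both directions. Coagulation and fibrinolysis genes included 8 higher and 4 lower of 19 (8 and 5 adjusted over the list alone, camera adjusted p = 0.0818). The serpin gene Serpini1 rose from 0.302 ± 0.0976 to 11.8 ± 5.18 CPM, Thbs1 (thrombospondin) from 2.71 ± 0.321 to 59.5 ± 40.7 CPM, and the thrombin receptor gene F2r from 1108 ± 130 to 2698 ± 292 CPM. Thbs1 rose 21.9-fold with all libraries and 11.8-fold without replicates 2 and 3. Mesenchymal genes included 6 higher and 1 lower of 21 (the same adjusted over the list alone, 8 and 1 by DESeq2, 4 and 1 by limma-voom, camera adjusted p = 0.287, but 0.0371 with a sex term), with Col5a1 up 12.1-fold, Ccn2 up from 172 ± 48.4 to 742 ± 288 CPM and the transcription factor gene Snai2 down 3.04-fold. TGF-beta and BMP genes included 5 higher and 6 lower of 21 (6 and 7 adjusted over the list alone, camera adjusted p = 0.585). Bmp4 fell 10.1-fold and Bmp6 from 357 ± 111 to 90.9 ± 40.1 CPM, Tgfbr1 fell 1.45-fold, and Smad3 rose 2.36-fold. Notch genes included 2 higher and 5 lower of 14 (the same adjusted over the list alone, camera adjusted p = 0.0818), with the glycosyltransferase gene Lfng down 7.61-fold, the ligand gene Dll1 down 4.97-fold and the feedback gene Nrarp up 1.98-fold. Leaving out 1 library took the camera test of the Notch list past the threshold without control replicate 3 (adjusted p = 0.0464) or without replicate 2 or 3 of the libraries labelled knockout (0.00557 and 0.0204), and that of the coagulation list without replicate 1, 4 or 5 of the latter (0.0417, 0.0345 and 0.0253). The Notch list passed as well without replicates 2 and 3 together (camera adjusted p = 0.00224) and without a count filter (0.0122), and the coagulation list without a count filter (0.0240) and with a sex term (0.0244).

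Junction genes included 2 higher and 6 lower of 20 (the same adjusted over the list alone, camera adjusted p = 0.287). Jup fell 2.54-fold, Jam3 2.06-fold and Esam 1.47-fold, and Nectin2 rose 1.59-fold. Angiogenesis genes included 3 higher and 5 lower of 19 (the same adjusted over the list alone, camera adjusted p = 0.176, but 0.00979, as lower, without replicates 2 and 3 of the libraries labelled knockout). The adrenomedullin co-receptor gene Ramp2 fell 2.26-fold and Nrp2 1.86-fold, and hepatocyte growth factor, Hgf, rose from 91.7 ± 23.5 to 820 ± 309 CPM. Genes of NF-kB inflammation included 4 higher and 7 lower of 23 (the same adjusted over the list alone, camera adjusted p = 0.585). The leukocyte adhesion genes Vcam1 and Icam1 fell 4.19-fold and 2.08-fold, Tnf fell 10.4-fold, and Birc3 rose 1.75-fold. Genes of continuous capillaries included 2 higher and 2 lower of 13 (2 and 3 adjusted over the list alone, camera adjusted p = 0.745). Plvap, which builds the diaphragms of fenestrae, rose from 389 ± 39.1 to 1909 ± 521 CPM, and Gpihbp1, which anchors lipoprotein lipase, fell from 890 ± 85.5 to 155 ± 45.4 CPM. Flow-responsive genes included 3 higher and 3 lower of 14 (3 and 4 adjusted over the list alone, camera adjusted p = 0.745), with endothelin, Edn1, up 2.75-fold and nitric oxide synthase, Nos3, down 2.37-fold.

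Lymphatic genes included 1 higher and 2 lower of 8 (2 and 2 adjusted over the list alone, camera adjusted p = 0.367). Without replicates 2 and 3 of the libraries labelled knockout the median log2 fold change of the list turned from 0.175 to -0.524, with camera adjusted p = 0.00979. The VEGF receptor gene Flt4 fell from 3509 ± 302 to 1546 ± 111 CPM, Itga9 fell 1.74-fold, and Prox1 rose 2.32-fold to 8.44 ± 3.43 CPM. Of 19 measured ETS family genes other than Erg and Fli1, Elk3 fell 1.65-fold, Etv3 fell 1.43-fold, and Etv5 rose 1.55-fold, with the other 16 not past the threshold (the same counts adjusted over the list alone, but 6 higher and 3 lower by DESeq2, 2 and 2 by limma-voom, and 6 and 6 at an unadjusted p under 0.05, camera adjusted p = 0.901). The Etv5 call ended without control replicate 1, 2 or 3 or without replicate 1 or 5 of the libraries labelled knockout, at edgeR adjusted p between 0.0528 and 0.0767. The p53 and apoptosis list had 3 higher and 2 lower of 21 (the same adjusted over the list alone, camera adjusted p = 0.413), including Sesn2 up 2.98-fold, Bcl2l11 up 1.54-fold and the death receptor gene Fas down 2.97-fold. The endoplasmic reticulum stress list had 2 higher and 1 lower of 18 (0 and 1 adjusted over the list alone, camera adjusted p = 0.901), the lower one being Herpud1 at 1.65-fold. The immediate early genes that dissociation can induce had 1 lower and 0 higher of 20, and 0 called adjusted over the list alone (camera adjusted p = 0.259, but 0.0473 without control replicate 3, and 0.00994 without replicate 2 and 0.00485 without replicates 2 and 3 of the libraries labelled knockout).

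Markers of other cell types moved with the groups for some types and not for others. Kupffer cell and macrophage markers had 0 of 18 called by edgeR (0 at an unadjusted p under 0.05, 0 adjusted over the list alone and 0 by DESeq2 or limma-voom, camera adjusted p = 0.901) and summed to 388 ± 196 CPM in controls and 409 ± 334 CPM in libraries labelled knockout. Hepatocyte markers summed to 315 ± 119 and 238 ± 88.8 CPM, with the urea cycle gene Ass1 higher (13.4 ± 3.26 to 94.3 ± 47.4 CPM) and Apoa2 lower of 19 measured (1 higher and 0 lower adjusted over the list alone, but 1 and 7 by DESeq2 and at an unadjusted p under 0.05, and 1 and 5 by limma-voom, camera adjusted p = 0.0818, but 0.0151 without control replicate 4, 0.00579 without replicate 4 of the libraries labelled knockout, 0.00931 without a count filter and 0.0426 scaled by library size alone). The Apoa2 call ended without control replicate 1, 2 or 3, without replicate 2, 3, 5 or both 2 and 3 of the libraries labelled knockout, with a sex term and without a count filter, at edgeR adjusted p between 0.0603 and 0.130. Lymphocyte markers summed to 25.1 ± 8.63 and 32.9 ± 12.7 CPM with 1 of 9 lower, Lck (the same adjusted over the list alone, camera adjusted p = 0.571), and 0 of 5 measured cholangiocyte markers were called by edgeR (likewise 0 at an unadjusted p under 0.05, adjusted over the list alone, by DESeq2 and by limma-voom, camera adjusted p = 0.745). Erythroid markers summed to 42.0 ± 7.90 and 47.9 ± 16.8 CPM with 1 of 7 higher, the transferrin receptor gene Tfrc (the same adjusted over the list alone, camera adjusted p = 0.901), whose call ended without control replicate 2 or 3 (edgeR adjusted p = 0.0595 and 0.0605) and without a count filter (0.0549).

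Neutrophil and monocyte markers were higher for 8 of 15 measured genes and lower for 0 (the same adjusted over the list alone). As a set they gave camera adjusted p = 3.78e-05, and adjusted p = 0.549 with an estimated correlation. Their sum stayed small, 12.7 ± 4.52 CPM in controls and 36.1 ± 14.3 CPM in libraries labelled knockout. The granule gene Ngp had 0 counts in the 4 controls and 607 in the 5 libraries labelled knockout, at least 166-fold higher against a floor of 3 counts over the control group. Ltf, lactoferrin, had 3 control counts and 351 counts in libraries labelled knockout, a ratio of 95.9 with a 95% counting interval of 32.6 to 467. In edgeR it rose 79.7-fold, or 152-fold without control replicate 3. Platelet and megakaryocyte markers were higher for 7 of 12 and lower for 1 (the same adjusted over the list alone and by DESeq2, 5 and 1 by limma-voom). In the list test they gave camera adjusted p = 3.47e-04, and adjusted p = 0.549 with an estimated correlation. The chemokine gene Pf4 rose from 2.76 ± 0.642 to 24.8 ± 3.18 CPM, the integrin gene Itgb3 from 185 ± 40.5 to 1010 ± 491 CPM, Tubb1 rose 4.48-fold, and Selp fell 2.48-fold. The sum of the list went from 448 ± 45.1 to 1250 ± 597 CPM, and Itgb3 made up most of that rise. Stellate cell and fibroblast markers had 5 higher and 1 lower of 18 (the same adjusted over the list alone, camera adjusted p = 0.287, but 0.0173 with the filter of 5 CPM) and summed to 1347 ± 160 and 3178 ± 729 CPM. Bgn, named after its values were seen, rose from 1016 to 1937 CPM, with Ecm1 up 2.41-fold, Pdgfra up 5.04-fold from 0.381 ± 0.252 CPM and Vipr1 down 1.85-fold. Hgf, which rose from 91.7 ± 23.5 to 820 ± 309 CPM, belongs to this list too. Bgn and Hgf made up most of the rise of its sum.

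**Figure D4:**
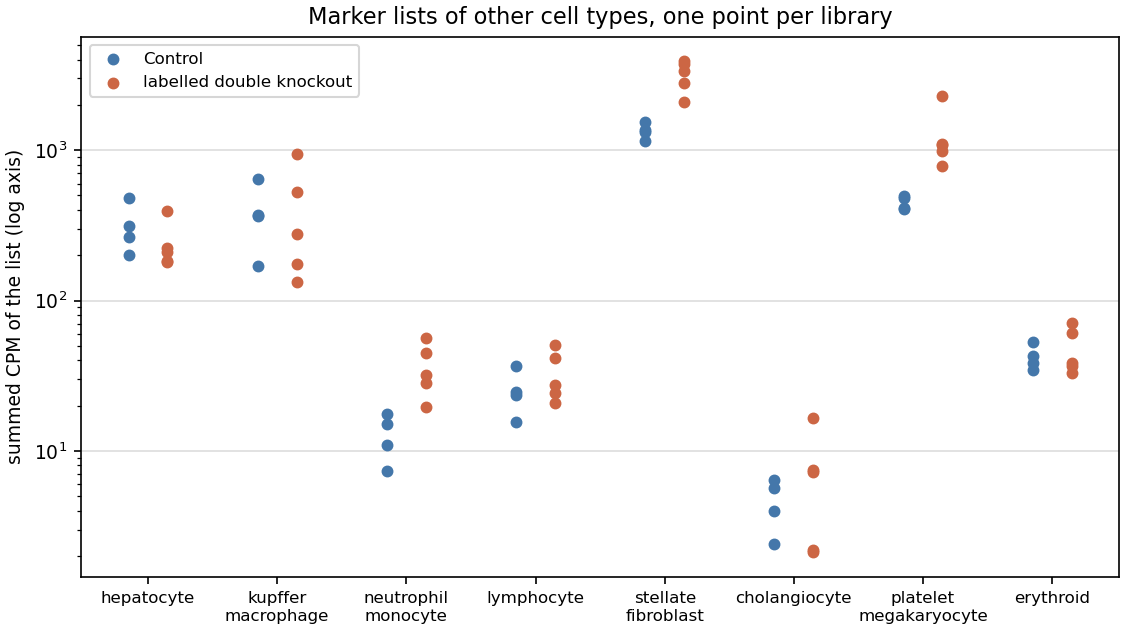
Summed TMM-scaled CPM, on a log axis, of 8 marker lists for cell types other than endothelial cells, one point per library, with controls in blue (4 libraries) and libraries labelled double knockout in orange (5 libraries). Platelet, stellate and neutrophil sums lie higher in every library labelled double knockout than in every control, and the other 5 lists overlap. Itgb3 made up most of the platelet rise, and Bgn and Hgf most of the stellate rise.

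All calls above are from edgeR's quasi-likelihood test, and all list tests are camera on the same fit. The gene-level counts came without a stated strand setting, so it is not known whether overlapping genes on opposite strands were counted apart. Camera passed 10 of the 30 lists at the preset correlation and 0 under an estimated one (2 at an unadjusted p under 0.05). The list calls therefore depend on how far genes of a list are taken to vary together. Fry, which tests a list against no change, passed 14.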

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

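These gaps between 1 library and the rest of its group were searched for among the genes, list sums and library measures after the data were seen, and none of them was tested for a cause. Of 387 groups of values, 13 held a library far from the others, and chance gives about 19.4. Control replicate 4 was the library in 7 of the 13.

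In control replicate 4, Notch1 lay at 967 CPM against 655 to 680 CPM in the other controls. Xbp1 lay at 217 CPM there against 127 to 128 CPM. Gas6 lay at 432 CPM against 614 to 640 CPM, and Bcl2l11 at 54.0 CPM against 57.6 to 58.0 CPM. The summed pericentral genes came to 2940 CPM against 3746 to 3921 CPM. Summed Notch genes came to 2518 CPM against 1795 to 1890 CPM, and summed cell cycle genes to 608 CPM against 948 to 982 CPM. The call of Xbp1 as higher in the libraries labelled knockout (edgeR adjusted p = 0.0397) ended without control replicate 1, 2 or 3, without replicate 2, 3, 5 or both 2 and 3 of the libraries labelled knockout and with a sex term, at adjusted p between 0.0542 and 0.114.

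Chpf lay at 0.295 CPM in control replicate 1 against 0.4997 to 0.5042 CPM, and Tubb1 at 0.851 CPM in control replicate 3 against 0.491 to 0.502 CPM. Among the libraries labelled knockout, Jam3 lay at 4.98 CPM in replicate 1 against 6.65 to 7.25 CPM. Herpud1 lay at 47.8 CPM in replicate 3 against 76.9 to 89.6 CPM. Summed hepatocyte markers came to 394 CPM in replicate 4 against 181 to 222 CPM. Mmp8 lay at 0.568 CPM in replicate 5 against 1.14 to 1.47 CPM.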

How the results depend on the processing

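The sex term and the fit without replicates 2 and 3 of the libraries labelled knockout were chosen only after the result was seen, and the other alternatives were chosen before the data were examined. Of the 4271 called genes, 0 were called in the opposite direction by an alternative that tested them. A change of sign without a call was not counted, and the filter of 5 CPM tested only 10222 genes. DESeq2 called 2543 higher and 2486 lower genes, limma-voom 1980 and 2279, library size alone 2623 and 1808, and the fits without 1 library each between 1495 and 1981 higher and between 1591 and 2040 lower. With a sex term 84.2% of the called genes kept their call and direction, and without replicates 2 and 3 of the libraries labelled knockout 81.6% did.

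Against a log2 fold change of 1, glmTreat called 289 higher and 213 lower genes, with Erg at -1.125 (adjusted p = 0.340) and Fli1 at 0.5581 (adjusted p = 1), since that test asks for a change above 2-fold. With the replicate block, edgeR called 1296 higher and 1375 lower genes and kept 60.7% of the calls. Fli1 then stood at 0.5021 (adjusted p = 0.0639). Among the genes named in the text the block also ended the calls of Ecm1 (adjusted p = 0.0618), Mcm4 (0.0667), Etv3 (0.0700), Prox1 and Lgmn (0.0778 each), Clec1b (0.0838), Tfrc (0.108), Gbp9 (0.117), Xbp1 (0.125), Apoa2 (0.136) and Etv5 (0.139), and took the coagulation and mesenchymal lists past the camera threshold (0.0195 and 0.0248). Over the 19 alternatives other than glmTreat its adjusted p lay between 1.61e-04 and 0.0639, and that of Erg between 2.76e-39 and 0.00285. The replicate numbers share no stated origin: same-numbered libraries correlated at 0.291, -0.0308, -0.0183 and -0.333 in their deviations, and of the 4 controls only replicate 1 correlated best with its own number. Camera with an estimated correlation left 0 lists past the threshold (2 at an unadjusted p under 0.05, 14 in fry). Beyond the lists that camera called, fry, which tests a list against no change, passed the junction and angiogenesis lists (0.00766 each). It also passed Notch genes and stellate markers (0.0277 each) and coagulation genes (0.0306), and it lost the cell cycle list (0.0661). Over all alternatives the adjusted p of lists not called in the report lay between 0.0248 and 0.865 for mesenchymal, 0.0195 and 0.559 for coagulation, 0.00224 and 0.559 for Notch, 0.00766 and 0.549 for angiogenesis and for junction, 0.00979 and 0.865 for lymphatic and 0.00485 and 0.901 for immediate early genes, and between 0.00579 and 0.879 for hepatocyte and 0.0173 and 0.549 for stellate markers. The block leaves fewer degrees of freedom for the test. Replicate 5 of the libraries labelled knockout has no control of its number, so under the block it adds nothing to the comparison. How far this accounts for the block's losses was not tested.

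Values of uncalled genes (log2 fold change) and lists (median, while the direction is camera's) reversed as follows, and the cause was not tested. Library size alone gave Cdh5 0.04325 and Kupffer markers 0.2013. The filter of 5 CPM gave the ETS family -0.05424, endoplasmic reticulum stress -0.02014, Kupffer markers 0.1449 and lymphocyte markers 0.3509. The block gave Hba-a2 -0.08262, the sex term Hbb-bt 0.06415, and limma-voom Hba-a2 -0.2815 and Krt19 -0.07672. Without replicates 2 and 3 of the libraries labelled knockout, Cdh5 was 0.05513, Hba-a2 -0.6945, Spp1 -0.1992, Trem2 -0.04868, TGF-beta and BMP genes -0.02636, endoplasmic reticulum stress 0.1142, Kupffer markers -0.2048, cholangiocyte markers -0.1992 and erythroid markers -0.4983. Leaving out 1 library gave ranges of -0.06721 to 0.02285 for Cdh5, -0.3079 to 0.3689 for Hba-a2, -0.5199 to 0.2442 for Hbb-bt, -0.1165 to 0.01565 for endoplasmic reticulum stress, -0.4227 to 0.3453 for Kupffer markers and -0.4261 to 0.2506 for erythroid markers. Gene values under alternatives were tallied for 159 selected genes only, most of them chosen by size of change or by smallest p. Of these values, 2971 stayed on their side of the threshold, 128 lost it, 33 gained it and 16 reversed. For lists these were 512, 12, 28 and 16. The tally therefore does not describe all tested genes.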

Other observations

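The tests of platelet RNA, of the Y-linked transcripts and of the imprinted genes were chosen only after the result was seen, as were the split by locus, the genome windows and the search over gene families. The predictions for the genes near the targeted loci and for the count of splits were written after the first gene results were seen, but before these 2 tests were run.

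Several imprinted genes, which are expressed from 1 parental copy, rose steeply. Mest rose from 109 ± 20.8 CPM (n = 4) to 2274 ± 906 CPM (n = 5) in the libraries labelled knockout, and Peg10 from 12.7 ± 4.11 to 551 ± 433 CPM. Peg10 rose 43.5-fold with all libraries and 28.5-fold without replicate 3 of the libraries labelled knockout. Sgce, Ppp1r9a and Grb10 rose by log2 fold changes of 1.09, 2.29 and 1.28. In a list of 52 imprinted genes written after these 5 were seen, 31 were tested by edgeR, 7 were higher and 2 lower, and the lower ones were Kcnq1 (-1.69) and Peg12 (-0.50). The hypothesis that imprinted genes move together was first tested on the whole list, where camera with an estimated correlation gave p = 0.0119. That list holds the 5 genes that prompted it, so the test was then repeated without them, a change made after its first result. The other 26 had a median log2 fold change of 0.16, and camera with an estimated correlation gave p = 0.619. Of them 2 were called higher and 2 lower. For these 26 genes no joint move in one direction was detected. The test cannot exclude one, because a large p does not show that a shared shift is absent. The result for the whole list rests on the 5 genes that prompted it.

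Of 158 families formed by the shared start of their symbols, that of the guanylate-binding proteins (Gbp), interferon-induced GTPases, alone passed camera (8 lower and 1 higher of 11, adjusted p = 5.88e-04, and adjusted p = 0.995 with an estimated correlation). Gbp6 fell from 13.6 to 3.40 CPM, Gbp4 2.29-fold and Gbp9 1.49-fold, all named after their values were seen. The Gbp9 call ended without control replicate 1 or 2 (edgeR adjusted p = 0.0555 and 0.0648) and with a sex term (0.0612). Reads of these similar genes can be shared, so single members are uncertain, and Gbp2 and Gbp3 belong to the interferon list as well.

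Platelet and megakaryocyte transcripts rose together with Itgb3 and Itga2b, and platelets attached to sorted cells are a candidate source. The VE-cadherin gate would remove free platelets but not attached ones, and Vwf and Selp of the marker list also stand in endothelial lists. Itgb3 and Itga2b together gained 879 ± 222 CPM (SE), against 24.3 ± 1.78 CPM (SE) for Pf4 and Ppbp, which are abundant in platelets, a ratio of 36.1. Most of that gain was of Itgb3 (185 ± 40.5 to 1010 ± 491 CPM), and the platelet share falls far short of it. Itga2b rose only from 26.4 ± 6.37 to 79.5 ± 30.4 CPM, so the pooled gain does not settle the source of its rise. For Pf4, Ppbp, Tubb1, Gp9, Gp6, Gp5 and Gp1bb platelet RNA cannot be told apart from a change in the endothelial cells: 5 of the 7 passed edgeR's threshold as higher, and Gp5 and Gp1bb did not (adjusted p = 0.108 and 0.124 in edgeR), with a chi-square heterogeneity p = 4.82e-05 between the sizes of these changes.

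Replicate 3 of the libraries labelled knockout was female by its Xist count yet held 178 counts of Ddx3y, 41 of Uty, 90 of Kdm5d and 109 of Eif2s3y. These were 3.69% to 5.74% of the mean male level, 4.47% on average, and the largest share was 1.56 times the smallest, within the 1.71 times by which male libraries differed. This is consistent with male RNA, cells or reads mixed into that library. Carry-over between all libraries is argued against by the other females, which held at most 1 count of each gene, and whose share of the male level, averaged over the 4 genes, was at most 0.0494%. No biological explanation was tested.

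The share of called genes was larger than elsewhere near Erg but not near Fli1. Within 5 Mb of Erg or Fli1, 36 of 89 genes were called by edgeR, 40.4% (95% exact interval 30.2 to 51.4), against 29.2% elsewhere. Fisher's exact test, two-sided, gave p = 0.0259 and takes neighbouring genes as independent. By locus, 27 of 54 genes (50%) were called near Erg and 9 of 35 (25.7%) near Fli1, a difference that was not tested. Flanking DNA of another strain around a targeted allele is a candidate reason for the share near Erg. The share near Fli1 lay below that elsewhere and gives this reason no support. The joint share lay within the genome's range. Of 225 windows of 10 Mb with at least 20 genes, 13 reached it, and the 95th percentile of the windows was 40.6%. Kcnj15, 0.19 Mb from Erg, fell 4.84-fold from 39.7 ± 1.73 CPM, and Kcnj5, 0.15 Mb from Fli1, rose from 0.671 ± 0.345 to 14.6 ± 3.49 CPM, both named after their values were seen. Regulation of neighbouring genes by the targeted loci stays open and was not tested.

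The real split called more genes than any other split tried. Of 100 splits of the 9 libraries into 4 and 5, the real one included, 1 called as many genes as the real 4271, and the highest of the others called 1484. A share of 1 in 100 is the smallest that this test can give. Every other split puts libraries of both groups together, which widens the spread within a group and makes few calls likely beforehand. The test therefore cannot tell the label apart from anything else that differed between the groups.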
